A study of Danio rerio with 416 samples.

How the data were processed

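Single cells from zebrafish embryos at 50% epiboly were measured in 416 samples, each of which is 1 cell. Of these, 52 wild-type cells and 276 maternal-zygotic one-eyed pinhead (MZoep) cells had full-length SMART-seq2 libraries in 4 library batches, called p1 to p4 after the sample titles. A further 88 MZoep cells had 5-prime libraries with unique molecular identifiers (UMIs), called batch p0. Genotype and library type were taken from the labels, and the batch from the sample titles. Whether cells of both genotypes with the same batch name were processed together is not stated, and the within-batch and standardised values rest on it.

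The full-length values were deposited as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) per gene and cell. Per the submitters' processing notes, Bowtie2, RSEM and build GRCz10 were used; their versions, the annotation and any filters are not given in the sources used here. The 5-prime values were deposited as counts of UMIs per gene and cell, and how UMIs were collapsed is not given in the sources used here. In the deposited count table the columns of the 328 full-length cells hold only 0 and were not used. The FPKM table has 25208 gene rows, and there are 19205 in the count table. Symbols are in capitals in the files and are printed here in the lower case used for zebrafish. No genome of the build used was at hand, so no coordinates are given; RefSeq annotation of assembly GRCz12tu was used only to find which genes neighbour tdgf1.

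The summed FPKM per cell was between 546642 and 646223 among the kept cells. The 10 rows with the highest mean FPKM took a median of 58.8% of the sum in wild-type cells and 56.9% in MZoep cells, and the highest row alone a median of 42.9% and 38.8%. Since FPKM values are relative, a difference in those rows moves all other genes together.

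Sequencing depth is not stated, but low FPKM values of 1 gene are multiples of what 1 read is worth. Over 7061 genes seen in 10% to 50% of cells, 45338 of 550728 values above 0 lay within 10% of 2 steps, against 18709 in a window of equal log width halfway between 1 and 2 steps. The position of the first step gave each cell's depth relative to the median cell. It was lower in wild type than in MZoep in p2 (medians 0.563 and 0.735), near equal in p3 (1.25 and 1.24) and p4 (1.14 and 1.20), and higher in wild type in p1 (1.38 and 1.20). This is relative depth only, so no counting interval can be given for a mean FPKM. A share of cells above an FPKM threshold depends on depth, and the exact binomial intervals given for shares cover counting error over cells only.

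Cells with at least 1500 genes at FPKM 1 or more were kept. This left 47 wild-type cells (3, 14, 18 and 12 in p1 to p4) and 245 MZoep cells (79, 80, 61 and 25), and left out 5 wild-type and 31 MZoep cells. The left-out cells had at most 1348 genes and 1 of them was listed at 0 for every gene. No pair of kept columns was identical. No doublet caller was run, and no clustering was made. Of the 5-prime cells, 86 with at least 500 genes were kept and 2 with 2 UMIs at most were left out.

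The labels name no embryo, clutch or culture, so each genotype is 1 sample and cells are not replicates. No test, p-value or SE was made from cells. For each gene and genotype, the mean FPKM over the cells of each batch was averaged over batches with the same weights in both genotypes (7.85%, 32.4%, 37.8% and 22.0% for p1 to p4, proportional to the product of the 2 cell numbers over their sum). The log2 ratio of MZoep over wild type used a pseudocount of 1 FPKM, which understates differences of low genes. Within-batch ratios are given beside it, but p1 holds only 3 wild-type cells. Shares of cells were pooled over batches without the batch weights. Because wild-type and MZoep embryos are not said to share a strain background or clutch, genotype, strain and clutch cannot be separated.

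Gene lists were fixed before the data were examined: 20 lists of named genes (Nodal targets, Nodal receptors, FGF, BMP and Wnt targets, dorsal margin, endoderm, ventrolateral margin, ventral and dorsal ectoderm, enveloping layer, germ cell, yolk syncytial layer, apoptotic-like, immediate early and heat shock, early zygotic factors, maternal transcripts, S phase, G2 and M phase, housekeeping), plus ribosomal protein and mitochondrial genes by symbol. Lists overlap: several mesendoderm genes are also Nodal targets, and most genes of the ventral ectoderm list are also in the BMP list. A measured member was at FPKM 1 or more in at least 5% of cells of 1 genotype. For each list the median log2 ratio, the number of members at least 2-fold apart and the percentile of the median among 10000 random lists of equal size, matched on mean expression in 20 bins, were computed. The percentile describes these libraries and is not a test of genotype. Cells were also counted as co-detecting a list when at least 3 members (2 for lists under 8 measured members) were at FPKM 1 or more, which is a range and not a cell type.

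Genes were named by a rule fixed before the data were examined: tdgf1; in each list, the 3 lowest and 3 highest measured members and any at least 2-fold apart; and over all genes, the 12 lowest and 12 highest ratios among genes at FPKM 1 or more in at least 20% of cells of 1 genotype, with a mean of at least 5 FPKM in 1 genotype, a ratio of the same sign in p2, p3 and p4, and a ratio still at least 2-fold after the cell with the highest value was left out. Other genes are said to have been chosen after their values were seen. The text does not print every gene so named, and the result of 1 withheld gene is not reported here. UMI counts were summed over cells and given per 1000000 (CPM) with exact Poisson intervals, which cover counting error only.

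The ratio step was tested on simulated data: cells were redrawn within batches without regard to genotype and 200 genes were multiplied by known folds, in a step of 6817 genes. The median recovered log2 ratio was 0.95 for 50 genes doubled and 1.94 for 50 genes multiplied by 4, and -0.97 and -1.68 for 50 genes each multiplied by 0.5 and 0.25; the last is short of the value built in because of the pseudocount. The list step was tested on 200 random lists of unaltered genes, 3% of which fell outside percentiles 2.5 to 97.5 in a step of 6817 genes. These lists were drawn from the same genes as their reference, so lists whose members are high in the same cells are not covered. Alternatives tried were a pooled mean, equal batch weights without p1, rescaling each cell to a sum of 1000000, a mean of log2 values, pseudocounts of 0.1 and 10, no filter on cells, at least 3000 genes per cell, leaving out each batch, leaving out the highest cell per gene, other gene filters, and detection at FPKM above 0 or at 10 or more. After seeing the data, 2 more were added: leaving out the 10 highest rows before rescaling, and using p3 and p4 alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.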

Results

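Single-cell transcriptomes of zebrafish embryos at 50% epiboly, the stage at which the blastoderm covers the upper part of the yolk and mesendoderm is being specified at its margin, were compared between wild type (TLAB) and MZoep. MZoep embryos lack maternal and zygotic function of one-eyed pinhead (tdgf1), the co-receptor that Nodal ligands need to signal. The comparison therefore asks which transcripts differ in cells of embryos that cannot receive Nodal signals. After filtering, 47 wild-type cells (3, 14, 18 and 12 in library batches p1 to p4) and 79, 80, 61 and 25 MZoep cells of the same batches remained. Batches were read from the sample titles, and that the same batch name in both genotypes means shared processing is not stated. The median number of genes at FPKM 1 or more was 6972, 7012, 6727 and 7162 in wild-type cells of p1 to p4 and 7011, 7528, 7511 and 6793 in MZoep cells. Each genotype counts as 1 sample, so the differences below have no replicate check, and intervals of shares cover counting error over cells only. Unless a batch is named, shares were pooled over all kept cells without batch weights. The batch make-up, which differs between the genotypes, therefore enters them.

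The gene mutated in MZoep, tdgf1, was present at a similar transcript level in both genotypes. Its mean was 45.4 FPKM in wild-type and 51.2 FPKM in MZoep cells (log2 ratio 0.17), and the within-batch ratios were -0.53, 0.53, 0.03 and 0.14 in p1 to p4. It was at FPKM 1 or more in 93.6% of wild-type cells (95% exact interval 82.5 to 98.7, n = 47) and 94.3% of MZoep cells (90.6 to 96.8). Its transcript level therefore does not separate the genotypes and gives no check of the labels. Over the 6943 genes at FPKM 1 or more in at least 20% of cells and with a mean of at least 5 FPKM, each in at least 1 genotype, the median log2 ratio was 0.13, so list values below are also given relative to it. Within batches this median was 0.24 in p2 and 0.27 in p3, and -0.02 and -0.01 in p1 and p4. With the 10 highest rows left out before rescaling, an alternative chosen after seeing the data, it was 0.08.

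Nodal targets were lower in MZoep. Of 27 measured Nodal ligands, feedback inhibitors and direct targets, 26 had a lower mean in MZoep and 20 were at least 2-fold lower, while none was at least 2-fold higher. The list median was a log2 ratio of -2.0 (-2.13 relative to all genes), below all matched random lists, whose central 95% lay between -0.07 and 0.37. Within p2, p3 and p4 the median was -0.75, -1.38 and -2.46. The Nodal feedback inhibitors lft1 and lft2 had ratios of -2.52 and -3.12, and fgf8a, a growth factor gene of the margin, had a ratio of -3.33. Transcripts of lft1 were at FPKM 1 or more in 10 of 47 wild-type cells (21.3%, 10.7 to 35.7) and in 2.0% of MZoep cells (0.7 to 4.7). For fgf8a the shares were 19.1% (9.1 to 33.3) and 1.2% (0.3 to 3.5). The ligand genes ndr2 and ndr1 had ratios of -2.12 and -1.19, but the ratio of ndr1 was 2.67 with no filter on cells, -0.71 without its highest cell and -0.22 in p2. Without their highest cell lft2 and ndr2 were at -2.47 and -1.46. The T-box gene tbx16 (121.8 and 108.8 FPKM, ratio -0.16), the actin-bundling gene fscn1a (-0.16) and eomesa (0.25) were the members least lower in MZoep. For many members the difference came from a minority of cells with high values, but noto was at FPKM 1 or more in 74.5% of wild-type cells. With the mean of log2 values in place of the log2 of the mean, the list median was -0.57 and 5 members were at least 2-fold lower, and with a pseudocount of 10 FPKM the values were -0.57 and 5.

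**Figure D1:**
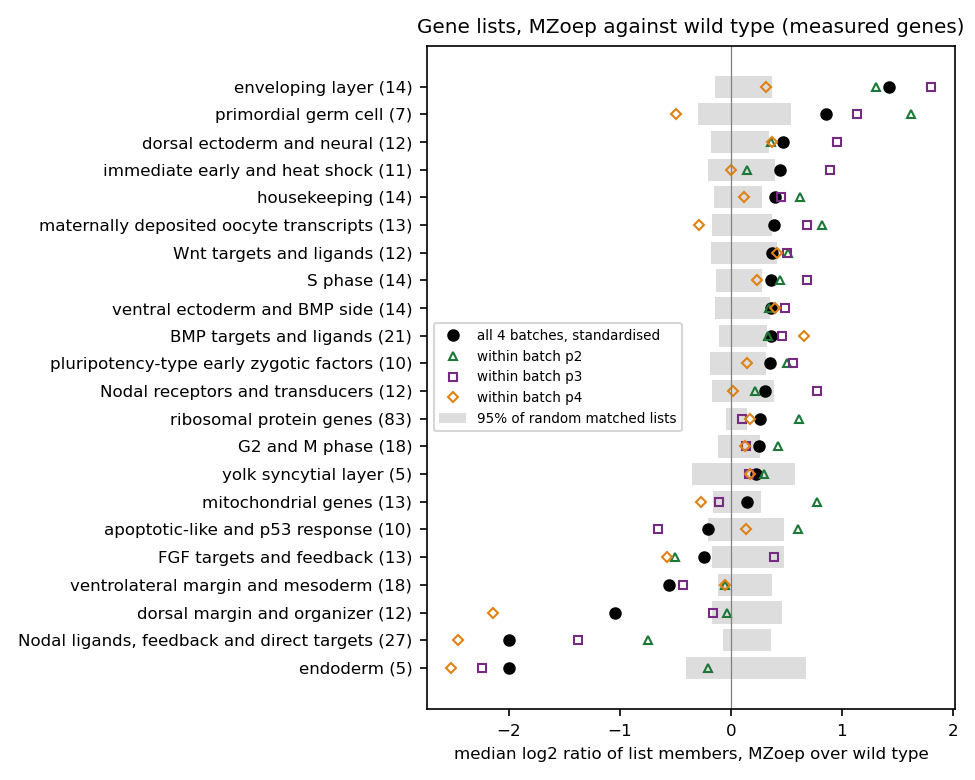
Median log2 ratio of MZoep over wild type for each gene list (x axis), with the number of measured genes in parentheses. Filled points show the value standardised over 4 batches, open symbols the values within p2, p3 and p4, and grey bars the central 95% of 10000 random lists matched on expression; the Nodal target list lies at -2.0 and the enveloping layer list at 1.43.

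Genes of the ventrolateral margin were lower, with exceptions. In this mesoderm list, 8 of 18 measured genes were at least 2-fold lower and 2 at least 2-fold higher (median -0.56, below all random lists). Within p2, p3 and p4 the median was -0.06, -0.43 and -0.05. The paraxial mesoderm factor mespab was at 14.6 FPKM in wild type and 0.116 FPKM in MZoep (ratio -3.80, -4.40 to -3.0 within p2 to p4). It was detected in 10 of 47 wild-type cells and in 0.82% of MZoep cells (0.10 to 2.92). Its partner mespaa (-2.24) was listed at 0 in all MZoep cells, and its wild-type transcripts were in 3 cells. For msgn1 (-3.49) the difference came from p3 alone (-4.73, against -0.11 in p2 and 0.0 in p4). The pan-mesodermal gene tbxta, chosen after its values were seen, had a ratio of -0.44, with 76.6% of wild-type (62 to 87.7) and 55.5% of MZoep cells (49 to 61.8) at FPKM 1 or more. In contrast the ventral and posterior genes eve1 and cdx4 were higher in MZoep, with ratios of 1.30 (31.9 and 79.9 FPKM) and 1.24, each higher within p2, p3 and p4. The margin gene wnt8a was lower (-1.53), with a ratio of -0.08 in p4. Without p3, 5 of the 18 genes were at least 2-fold lower.

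Dorsal margin and organizer genes had a median ratio of -1.05, with 7 of 12 at least 2-fold lower and none at least 2-fold higher. The median differed between batches, at -1.54 and -2.14 in p1 and p4 but -0.04 and -0.16 in p2 and p3. It was -0.18 with the mean of log2 values and -0.21 with the highest cell left out per gene. The notochord gene noto was at 68.7 FPKM in wild type and 11.5 FPKM in MZoep (-2.48), and it was lower in each batch (-4.49 to -1.76). It was detected in 74.5% of wild-type (59.7 to 86.1) and 50.2% of MZoep cells (43.8 to 56.6). The LIM homeobox gene lhx1a had a ratio of -3.05 and was detected in 40.4% (26.4 to 55.7) and 4.5% (2.3 to 7.9) of cells. The forkhead gene foxa3 had a ratio of -3.02, from -4.75 to -0.35 within p2 to p4, and of -2.07 without the wild-type cell of p4 that held 58.3% of the wild-type total. The BMP antagonist chrd was at 26.3 and 9.48 FPKM (-1.38), with a ratio of -0.07 in p2. For gsc (-1.50) a single wild-type cell of p4 held 71% of all wild-type FPKM, and without it the ratio was -0.15. Within p3 the ratio of gsc was 1.09, and it was detected in 25.5% (13.9 to 40.3) and 23.7% (18.5 to 29.5) of cells. The ratio of admp (-1.08) was -0.26 without its highest cell and -0.32 without p1, and 1.82 within p4. With the highest cell left out per gene, 4 of the 12 genes were at least 2-fold lower. At least 3 of the 12 genes were detected in 74.5% of wild-type (59.7 to 86.1) and 62.9% of MZoep cells (56.5 to 68.9). This order held in p1, p2 and p4 but not in p3, where the shares were 50.0% (26 to 74, n = 18) and 73.8% (60.9 to 84.2, n = 61). Cells close to the limit were common, since 12 wild-type cells had exactly 2 or 3 members.

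Of 5 measured endoderm genes, 4 were at least 2-fold lower in MZoep (median -2.0). As with both margin lists, some members, here sox32, gata5 and gata6, are also in the Nodal target list, so the lists are not independent. The median was -2.24 and -2.52 in p3 and p4, but -0.21 in p2 and 0.09 in p1. The endoderm factor sox32 had means of 16.5 and 2.12 FPKM (-2.48), but 1 wild-type cell of p3 carried 80.9% of the wild-type total, and without it the ratio was -0.43. Within p2 it was higher in MZoep (0.81). It was detected in 23.4% (12.3 to 38) and 22% (17 to 27.8) of cells. foxa2 (-2.45) was at FPKM 1 or more in 5 wild-type cells and in 1 MZoep cell. gata5 and gata6 had ratios of -2.0 and -1.09, and of -1.40 and -0.61 without their highest cell. cxcr4a, a chemokine receptor gene that is not restricted to endoderm, was higher in MZoep (0.98; 148.6 and 293.2 FPKM). The endoderm median was -0.61 with the highest cell left out per gene and -0.51 without p3, and 2 genes were at least 2-fold lower in either case. At least 2 of the 5 genes were detected in 42.6% of wild-type (28.3 to 57.8) and 42.9% of MZoep cells (36.6 to 49.3). The share was higher in MZoep in p2 (42.9% and 61.25%) and p3 (27.8% and 39.3%). It was lower in MZoep in p1 (66.7% and 39.2%) and p4 (58.3% and 4.0%).

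**Figure D2:**
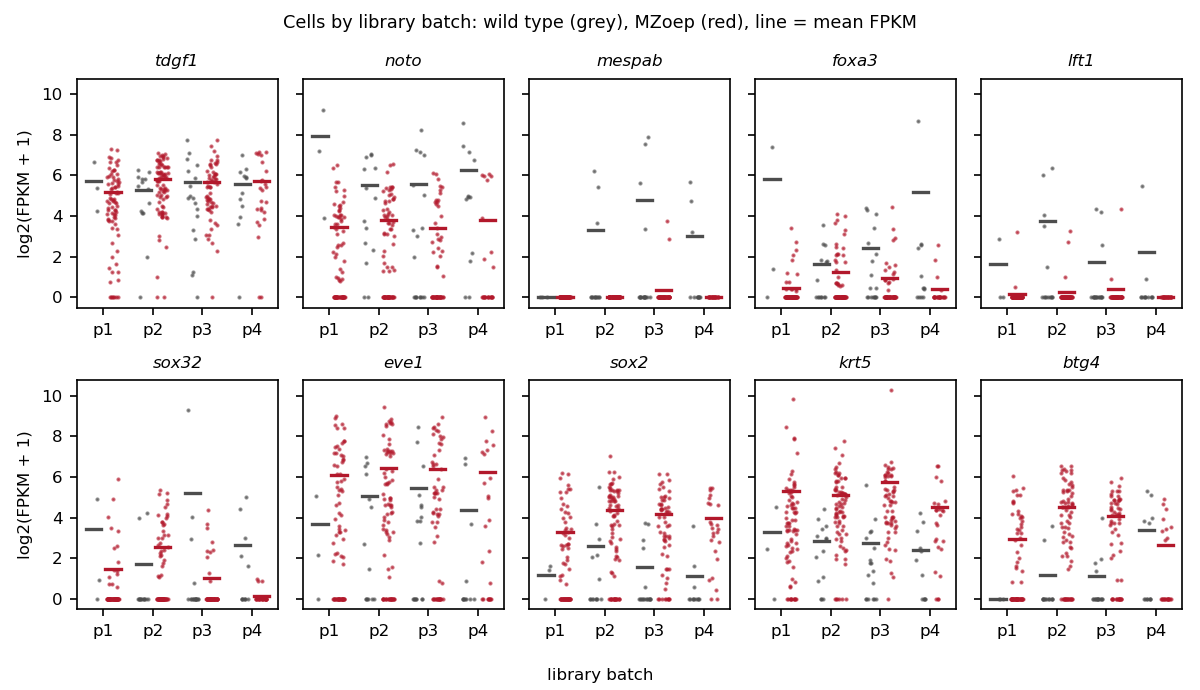
Values per cell, log2(FPKM + 1) on the y axis, by library batch on the x axis for 10 named genes, with wild-type cells in grey and MZoep cells in red; the line is log2(mean FPKM + 1). Most wild-type cells are at 0 for mespab (10 of 47 at FPKM 1 or more) and lft1 (10 of 47), while sox2 is detected in 69% of MZoep cells and 27.7% of wild-type cells.

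Ectoderm lists had medians slightly above that of all genes, and so did lists not tied to a tissue, with 0.40 for housekeeping genes (0.27 relative to all genes) and 0.36 for S phase genes (0.23). The dorsal ectoderm and neural list had a median of 0.47 (0.33 relative to all genes, percentile 99.9 of random lists), with 2 of 12 members at least 2-fold higher and none at least 2-fold lower. The neural progenitor gene sox2 was at 2.74 FPKM in wild type and 16.7 FPKM in MZoep (2.24), from 1.79 to 2.86 within p2 to p4. It was detected in 27.7% of wild-type (15.6 to 42.6) and 69% of MZoep cells (62.8 to 74.7). The Wnt-responsive gene sp5l had a ratio of 1.37. The ventral ectoderm and BMP side list had a median of 0.36 (0.23 relative to all genes, percentile 97.9), with gata2a at least 2-fold higher (1.31) and id3 at least 2-fold lower (-1.22, and -0.70 without its highest cell). BMP targets and ligands had a median of 0.36 (percentile 98.9). Most genes of the ventral ectoderm list are also in this list, so their values are not independent. The BMP-responsive homeobox genes msx1b (2.51) and msx3 (1.76) were higher together with eve1 and gata2a, and id3 was the single member of 21 at least 2-fold lower. The BMP-regulated gene szl had a ratio of 0.96, but of -0.55 in p3. Wnt targets and ligands had a median of 0.37 (percentile 95.2), with sp5l and cdx4 at least 2-fold higher and wnt8a and wnt5b at least 2-fold lower; wnt5b was at -0.64 without its highest cell and at 0.88 in p4. The FGF target list had a median of -0.24 (percentile 0.95), but it differed in sign between batches, at -0.43, -0.50, 0.39 and -0.58 within p1 to p4. In this list, 9 of 13 measured members had a lower mean in MZoep. The 3 members of the FGF list at least 2-fold lower were the ligand genes fgf8a, fgf3 (-2.14) and fgf24 (-1.43, and -0.77 without its highest cell). Each of these is also in the Nodal target or the ventrolateral margin list. The FGF-induced genes etv4 (0.45) and etv5a (0.55) were among the 4 members of the FGF list with a higher mean.

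Enveloping layer genes, which mark the outer epithelium of the embryo, were higher in MZoep. Of 14 measured genes, 13 had a higher mean and 9 were at least 2-fold higher, with a median ratio of 1.43 (1.30 relative to all genes), above all random lists. Within p2, p3 and p4 the median was 1.31, 1.81 and 0.32. The keratin genes krt5 (5.81 and 38.8 FPKM, 2.55), krt17 (2.13) and cyt1l (1.93) were higher within each of p2, p3 and p4, while krt4 (1.68) had a ratio of 0.05 in p4 and krt92 (1.53) of -0.65. krt5 was detected in 63.8% of wild-type (48.5 to 77.3) and 90.2% of MZoep cells (85.8 to 93.6). The annexin gene anxa1a was lower (-1.54), but at -0.03 in p2 and 1.29 in p1. With a pseudocount of 10 FPKM the list median was 0.79.

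Maternally deposited oocyte transcripts had a median ratio of 0.39 (0.26 relative to all genes, near the 0.27 of housekeeping genes; percentile 98.3), and 4 of 13 were at least 2-fold higher in MZoep. These were org (10.3 and 57.5 FPKM, 2.37), btg4 (2.01), slbp2 (1.91) and mos (1.18). The list median was 0.82 in p2 and 0.69 in p3 but -0.29 in p4, where btg4 (-0.72), slbp2 (-0.29) and mos (-0.38) were lower in MZoep and org was higher (1.66). Primordial germ cell genes had a median of 0.86 (percentile 99.9), with nanos3 (3.63), dnd1 (1.91) and ca15b (1.37) at least 2-fold higher, while ddx4 (-0.05) and dazl (-0.03) were not. Without p2 the median was 0.15, near that of all genes. Of the MZoep total of nanos3, 2 cells of p2 held 42.1% and 38.4% (3201 and 2925 FPKM), and the same cells held 35.2% and 39.9% of dnd1. The highest wild-type value of nanos3 was 20.4 FPKM. In p4 the germ cell median was -0.49 and dnd1 was lower in MZoep (-0.69).

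Nodal receptors and transducers had a median of 0.31 (percentile 92) with acvr2ab at the upper end (1.15 and 3.29 FPKM) and smad3b at the lower (-0.43). Early zygotic factors had a median of 0.35 (percentile 98.8), with klf17 at 1.25 (0.15 in p4) and vgll4l at -0.72. S phase genes had a median of 0.36 (percentile 99.8), G2 and M phase genes 0.25 (96.6), housekeeping genes 0.40 (99.9), ribosomal protein genes 0.26 (above all random lists) and mitochondrial genes 0.14 (79.2). Within p1 to p4 the housekeeping median was -0.10, 0.62, 0.45 and 0.12. The ribosomal protein median was 0.05, 0.62, 0.10 and 0.17, so both were highest in p2. The mitochondrial median was 0.77 in p2 but -0.11 and -0.27 in p3 and p4, and it was below 0 under 2 of 17 alternatives. Among housekeeping genes, actb1 (1.07) and hprt1 (1.04) were at least 2-fold higher and ppiaa had a ratio of -0.17. The immediate early and heat shock list had a median of 0.45 (percentile 98.8), but of 0.08, 0.14, 0.89 and 0 within p1 to p4. Among its members, ier2 was lower (-1.49, and -0.35 in p2) and hsp70.2 higher (1.21, with 0.44, 2.15 and -0.27 within p2 to p4). Apoptotic-like and p53 response genes had a median of -0.21 (percentile 2.6), with 1.53, 0.61, -0.66 and 0.14 within p1 to p4, and the median was above 0 under 2 of 17 alternatives. Yolk syncytial layer genes had a median of 0.23 (percentile 70.8) over 5 measured members. For most lists nearly every cell of either genotype co-detected members, so those shares separate nothing: the enveloping layer share was 97.9% (88.7 to 99.9) in wild type and 97.6% (94.7 to 99.1) in MZoep.

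Among all genes that passed the filters of the naming rule, the lowest ratios in MZoep were led by genes outside the lists. The uncharacterised gene si:dkey-108k21.23 was at 441.5 FPKM and in all 47 wild-type cells, and at 0.723 FPKM in MZoep, where 11% of cells had FPKM 1 or more (7.4 to 15.6). Whether reads of this gene can be told from those of the 12 other genes of its clone was not measured, so its value is uncertain. The others were the cytochrome P450 gene cyp2aa8 (-4.18), zgc:194989 (-4.03), mespab, the transcript ENSDART00000129497 (-3.13), lhx1a, si:dkey-182g1.8 (-3.04), foxa3, si:ch73-36p18.4 (-3.01), si:dkeyp-52c3.2 (-2.91) and the glutamine synthetase gene glula (-2.71; 91.5% of wild-type and 26.1% of MZoep cells). 1 further uncharacterised gene of the lowest 12 was listed at 0 in all MZoep cells. The highest ratios were nanos3, ttc32 (3.20), si:dkey-207j16.5 (3.12), ms4a17a.9, tmem45a (2.75), znf1061 (2.58), krt5, krt96 (2.54), msx1b, bmi1b (2.51) and 2 further uncharacterised genes. ms4a17a.9 was listed at 0 in all 47 wild-type cells (upper limit 7.55%) and was in 31.4% of MZoep cells (25.7 to 37.6).

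The 5-prime MZoep libraries, whose levels are given as counts of UMIs per 1000000 (CPM), had a median of 47195 UMIs (29246 to 73231) and 6672 genes per cell over 86 cells. No wild-type cells were made this way, so their values stand on their own. Across 15046 genes, levels correlated with the full-length MZoep means on a log2 scale with a Pearson coefficient of 0.88 and with the full-length wild-type means of 0.84; genes are not independent replicates. tdgf1 had 208.4 CPM (Poisson interval 194.6 to 222.9) in all 86 cells. Nodal feedback genes were near the floor, with 1.72 CPM for lft1 (0.69 to 3.55) and 2.96 for lft2 (1.53 to 5.16), and mespab had 3 UMIs in all. noto had 69.95 CPM (62.1 to 78.6) and was found in 55 of 86 cells (52.9 to 74). tbx16 had 1022 CPM and eve1 246.1. si:dkey-108k21.23 had 6 UMIs in 5 cells (1.48 CPM, 0.54 to 3.22).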

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

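The lists led with, and the SD over 4 batches as the spread for list medians, were chosen after list medians were seen. Leaving out the 10 highest genes was also added after seeing the data. Under all alternatives run, 20 of the 22 list medians kept their sign; those of the apoptotic-like and mitochondrial lists did not. Of 76 named genes at least 2-fold apart, 74 kept their direction. The exceptions were admp, at 0.13 with the mean of log2 values and 0.36 with p3 and p4 alone (an alternative chosen after seeing the data), and ndr1, at 2.67 with no filter on cells; the causes were not tested.

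With a pseudocount of 10, ratios of genes at low levels are smaller by construction, and the mean of log2 values gives less weight to a few high cells. With the mean of log2 values and the pseudocount, in that order, the medians were -0.57 and -0.57 for Nodal targets, -0.36 and -0.45 for endoderm, -0.32 and -0.30 for the ventrolateral margin and 0.50 and 0.25 for the ventral ectoderm, and with a pseudocount of 10 the enveloping layer median was 0.79. Members at least 2-fold lower were then 5 and 5 Nodal targets, 3 and 2 dorsal margin genes, 0 and 1 endoderm genes and 2 and 2 ventrolateral genes, and 1 maternal transcript was at least 2-fold higher with a pseudocount of 10.

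With the highest cell left out per gene, the endoderm median was -0.61 (2 genes at least 2-fold lower), the ventrolateral median -0.26, and 4 dorsal margin genes were at least 2-fold lower. With p3 and p4 alone the ventrolateral median was -0.86. Leaving out each batch gave medians of -1.45 to -0.47 for the dorsal margin, -2.53 to -0.51 for endoderm (2 to 4 genes), -0.98 to -0.35 for the ventrolateral margin (5 to 9 genes) and 0.23 to 0.46 for the ventral ectoderm. The causes were not tested.

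The share of MZoep cells with tdgf1 was 85.7% at FPKM 10 or more, 84.1% with no filter on cells and 92.7% to 96.99% with a batch left out. The dorsal margin share was 36.2% in wild type and 24.5% in MZoep at FPKM 10 or more. It was 71.4% in MZoep at FPKM above 0 and 55.8% with no filter on cells, and 63.6% to 89.7% in wild type with a batch left out. With 47 wild-type cells, a transcript present in few cells rests on a handful of them. Within each library batch the genotypes were compared side by side, without a test. No paired analysis was possible by cell number, because a number that occurs in both genotypes names 2 different cells.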

Other observations

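All tests below except that of carried RNA, and the cells and genes described first, were chosen after the result was seen. A few cells held transcripts of some list genes at levels far above most others, but no cell was assigned a type. The 3 MZoep cells with the highest krt4, in p3, p1 and p2, had 2989.7, 2382 and 809 FPKM, against 148.6 FPKM in the highest wild-type cell. 2 wild-type cells of p3 had 263.6 and 222.3 FPKM of the p53-responsive gene phlda3 and 52.96 and 65.7 FPKM of casp8, a caspase gene, and 2 MZoep cells with the highest phlda3, in p1 and p2, had 421.6 and 326.6 FPKM of phlda3 and 121.85 and 54.8 FPKM of casp8. A single wild-type cell of p4 had both the highest gsc (447.3 FPKM) and the highest foxa3 (410.1 FPKM). In the 5-prime MZoep libraries, the 2 highest cells held 85.8% of all nanos3 UMIs (580 and 512) and the 2 highest cells of dnd1 held 87.9% of its UMIs.

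Most keratin transcripts were found in most cells of the 5-prime MZoep libraries. krt4 was found in 98.8% of 86 cells (93.7 to 99.97) at 294.6 CPM, and its highest cell had 51 UMIs, 4.26% of all. krt5 and krt96 were found in 95.3% (88.5 to 98.7) and 87.2% (78.3 to 93.4) of cells, but krt17 in 16.3% (9.2 to 25.8). The highest cell held 5.82% of all UMIs of krt8, 6.22% of krt18 and 8.41% of the claudin gene cldne. Of the oocyte transcripts, org was found in 97.7% (91.9 to 99.7) and btg4 in 77.9% (67.7 to 86.1) of cells, while mos was found in 45.3% (34.6 to 56.5), zp3b in 47.7% (36.8 to 58.7) and zp2.1 in 14% (7.4 to 23.1).

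The enveloping layer list was higher in MZoep full-length cells, most in p2 and p3. A few enveloping layer cells sampled in MZoep alone would leave the median cell unaltered, but the log2 ratio of the median cells in summed list FPKM averaged 1.20 over p2 and p3 (1.14 and 1.26), which argues against them as the whole cause there. A shift of all genes is argued against by a list median of at least 1.07 over the all-gene median in both batches. RNA of enveloping layer cells carried into other cells stays open. The 50 other genes most enriched in the 3 highest krt4 cells were examined in p2 and p3 without those cells. Their median was 0.74 over the all-gene median, and 43 of them lay above it. A broad low-level activity of the same genes in MZoep cells would also give this. The 50 genes were picked by their values in MZoep and passed the expression filter with the 3 cells included, so part of it may come from that choice. The ratio of the median cells was -0.31 in p1, which held 3 wild-type cells and 1 of the 3 highest krt4 cells, and 0.20 in p4, so the difference may depend on which embryos went into each batch, which was not tested.

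Maternal oocyte transcripts were higher in MZoep in p2 and p3, and in p1 with its 3 wild-type cells, but not in p4. Shallower wild-type libraries stay open. Of the 2 batches with near equal relative depth, p3 had a list median of 0.69. This was just above the central 95% of matched random lists (-0.23 to 0.63). In p4 the list median was -0.29, within that of p4 (-0.40 to 0.39). Wild-type cells had fewer genes than MZoep cells in p3 and more in p4. In p1, where wild-type libraries were deeper (relative depth 1.38 and 1.20), the list median was 0.64, just above its range (-0.55 to 0.58). The p1 and p3 values go against depth as the whole cause, but both lie close to the limit and p1 held 3 wild-type cells. MZoep embryos at an earlier stage would also have less of the genes that come on towards gastrulation. Both ectoderm lists together lay 0.10 above the all-gene median in p2 and 0.37 in p3, with an SD of 0.14 over the 4 batches. The value in p2 is within that spread, a limit set after the value was seen. Ectoderm genes may also differ with genotype whatever the stage, so these values cannot decide the question and an earlier stage cannot be excluded. Slower clearance of maternal transcripts in MZoep, or clutches that differed between batches, stay open and were not tested.

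Of the 24 genes with the most extreme ratios among those that passed the filters of the naming rule, 18 belonged to no list, and several were near all-or-none between genotypes. A loss particular to the full-length MZoep libraries was examined in the 5-prime libraries. There, 6 of the 9 genes of the lower set had a row, with a median of 1.72 CPM. The 9 of the higher set, picked for high values in MZoep, had a median of 71.9 CPM. Without 5-prime wild-type cells, low levels there cannot be told apart from poor capture of these genes, so such a loss cannot be excluded. For si:dkey-108k21.23, reads shared with other genes of its clone, whose sequences were not compared, cannot be told apart from a true difference: summed over 13 genes of that clone the log2 ratio was -0.62, between -1.39 in p2 and 0.33 in p3, while the 12 others together were at 401.1 FPKM in wild type and 548.5 FPKM in MZoep. For linkage to the tdgf1 mutation, 0 of the placed genes lay among the 180 annotated neighbours of tdgf1, but only 11 of the 18 could be placed, so linkage cannot be excluded for the rest. A difference in strain stays a candidate explanation that was not tested, since the wild type is TLAB and the background of the mutant fish is not given.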
